A study of Homo sapiens with 4 samples.

How the data were processed

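FLAG CUT&Tag was performed on OVCAR8 cells with ectopic FLAG-BRD4L or FLAG-BRD4S, with 2 libraries per isoform, and each library came with its own peak list. Cells were bound to concanavalin A beads and tagmented with a protein A-Tn5 fusion, per the labels' protocols. Reads were aligned with BWA 0.7.13-r1126 to GRCh38 and peaks were called with MACS2, per the submitters' processing notes, which are taken as lists of names without settings. The peak names in the deposited lists show that each library was called separately and without a control library. MACS2's version, its options, read filters and the handling of duplicates are not given in the sources used here.

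Each deposited line gives a start, an end and a summit position, and 4 statistics. The deposited fold enrichment is the ratio of the summit pileup to the local background of the same library, each with a pseudocount of 1. The deposited −log10 p-value and −log10 q-value refer to the same comparison, and the deposited score is 10 times the −log10 q-value rounded down. The lowest −log10 q-values of the deposited lists were 1.01, 1.00, 1.00 and 1.00. These folds and p-values are the authors' and were used directly only to describe, rank or filter peaks within a list. The pileups and backgrounds solved from them were also compared between libraries, for depth, thinning and replicate noise. The lists hold no read counts, so no count model was used.

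Lines that split 1 interval by summit were to be collapsed, but 0 intervals were repeated. Chromosomes 1 to 22 and X were kept, which left 41199 of 41227, 45326 of 45355, 115482 of 115543 and 118146 of 118207 lines. The fold and the p-value of a peak together fix the summit pileup and the background, so both were solved for, and pileups came out as whole reads with a largest residual of 0.000558, 0.000538, 0.000812 and 0.000680 below a −log10 p of 300. On simulated lists the pileup was recovered for 99.99% and 100% of 20000 peaks. The most frequent background among peaks under 50 reads was taken as the genome-wide pileup. Reads were estimated as this pileup divided by the shortest peak width of the list (73, 73, 66 and 66 bp), which stands for the length the caller gave each read, times an assumed effective genome of 2.7 Gb. Ratios of depth do not rest on the assumed genome size.

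Gene positions and symbols came from a RefSeq gene table of GRCh38 with 19974 protein-coding genes, and all 741 genes of the 27 lists were matched. The table used here gives neither strand nor exons, and no genome sequence was used. The planned window around transcription starts was therefore replaced by a window of 1000 bp around either annotated gene end, and regions were assigned to gene end, gene body or intergenic sequence. A gene-end peak can thus lie at the 5' or the 3' end, or belong to a neighbouring gene. The planned motif shares and the matching on promoter GC content were not run. Gene-length matching with 10000 permutations in 10 bins took the place of the latter, and the planned window of the gene body with its upstream part was run with flanks of 10000 bp on both sides. The planned check of BRD4 exons was made by position.

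Overlap required 1 bp. Peak lists were merged into regions, and a region or gene was called shared with a peak in all 4 libraries, BRD4S-only with a peak in both BRD4S and neither BRD4L library, and BRD4L-only in the opposite case. Clusters were groups of at least 3 peaks with gaps below 10000 bp. Random placement used 20 shuffles on the same chromosomes. Differences per library were tested by exact permutation of the 4 library values, two-sided, with 6 ways to choose the libraries and 3 ways with BRD4S counted as 1 sample. Gene lists were tested with Fisher's exact test and Benjamini-Hochberg adjustment over the 27 lists at a threshold of 0.05. For BRD4S-only genes the background was the genes without a BRD4L peak. In simulations 100% of 360 planted lists of 25 genes (95% against 55%) and 2.22% of 720 unchanged lists were called. The background of the BRD4S-only test left 4 to 28 members per list, and with 17, 13, 9, 6 and 4 members 95.3%, 87.5%, 66.9%, 0% and 0% of such planted lists were called. The overlap and merging code gave the same results as bedtools on simulated intervals.

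Replicate noise was tested with the chi-square statistic of summit pileups at overlapping peaks with a summed pileup of at least 60, BRD4 left out, and 2000 permutations of the reads between the libraries. In simulations the statistic per degree of freedom was 1.12 with sampling alone and 7.80 with an added spread of 20%. The ratio of pileups between the BRD4S libraries was 1.24 and that of their backgrounds 1.35. For the BRD4L libraries these were 1.50 and 1.11. Because each library was called on its own and low peaks were selected by the caller, peaks near the threshold were left out of this test.

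Genes named in the text were fixed by rule: for each class the 8 genes with the highest value of the lowest within-list percentile of the deposited fold over the libraries that hold the peak, with at most 1 gene per region, up to 4 members per class of each list in the same order, and BRD4, CDK12 and MYC in any case. The groups, tests, gene lists, naming rule and the first set of other settings were chosen before the data were examined. That set held a −log10 q-value of at least 5, lists of equal length (41199 peaks), each library left out, other windows of 500 and 3000 bp, other cluster spacings of 5000 and 20000 bp, overlap of 50% of both peaks, summits within 250 bp, a peak in 1 library of an isoform, all sequences, every line as a peak, and a block on the replicate number. Chosen after the data had been seen were thinning of BRD4S to the BRD4L depth, a minimum pileup of 5 reads, the removal of flat-topped peaks, gene-length matching, the list test without the BRD4L libraries, the removal of BRD4 peaks, and the matching on BRD4S pileup.

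Thinning drew each BRD4S summit pileup binomially with 7.36% and 9.93% of reads kept and retained peaks that passed the lowest p-value of the BRD4L lists. It does not narrow or split peaks and cannot add peaks that were not called at full depth. Depth limited what could be seen with BRD4L, where a call could rest on 2 reads, and intervals cover counting error only. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.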

Results

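CUT&Tag profiles of FLAG-tagged BRD4 were compared in OVCAR8 cells, a line derived from high-grade serous ovarian cancer. BRD4 is a bromodomain protein that binds acetylated chromatin and recruits the transcription elongation machinery. The cells carried either the full-length form, BRD4L, or the short form, BRD4S, and 2 libraries were deposited for each. The series title places the work in the setting of a short BRD4 form made after loss of CDK12 activity by premature polyadenylation within an intron. The comparison implied by the design was where on the genome each form was found. On chromosomes 1 to 22 and X the peak lists held 41199 and 45326 peaks for BRD4L and 115482 and 118146 peaks for BRD4S.

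Depth differed by about an order of magnitude between the isoforms. The background read pileup recovered from the peak statistics was 0.0362 and 0.0326 in the BRD4L libraries and 0.422 and 0.313 in the BRD4S libraries. With an assumed effective genome of 2.7 Gb this corresponds to about 1.34 and 1.21 M reads for BRD4L and 17.3 and 12.8 M for BRD4S. A typical BRD4L peak held 2 reads at its summit, and 51.7% and 57.5% of the BRD4L peaks rested on 2 reads. Median summit pileups in the BRD4S lists were 13 and 9 reads. Summit pileups of the BRD4S libraries did not differ detectably beyond sampling noise over 20226 overlapping peaks (chi-square per degree of freedom 1.01, permutation of reads between the libraries, p = 0.147), so these libraries were counted as 1 sample. Within the 18798 of these peaks with summed pileups of 60 to 199, a small excess was seen (1.02, permutation p = 0.027). The BRD4L libraries differed by more than sampling noise over 626 peaks (1.47, permutation p = 0.0005, the smallest that 2000 permutations allow). Values are therefore given per library and without an SD, and where means are compared the BRD4S value is the mean of both libraries. The labels do not state whether libraries came from separate cultures, so the spread between them may be technical. The noise test also treats reads as independent. Of overlapping BRD4L peaks 61.7% and 61.6% had identical edges in the other BRD4L library, against 3.17% and 3.08% for BRD4S. A larger spread therefore does not show that the BRD4L libraries are the more independent pair.

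The BRD4 gene itself (chromosome 19, 15235519 to 15332539, GRCh38) held the highest pileups of both BRD4S lists. There were 8 narrow intervals between 15256067 and 15273100, and they accounted for 8 of the 10 highest pileups in each BRD4S library. At the interval 15265354 to 15265644 the pileup was 8844 reads in BRD4S library 1 and 6860 in library 2, and at 15264404 to 15264767 it was 6276 and 5108 reads. The lowest of the 8 held 609 and 525 reads, whereas the highest pileup outside BRD4 was 804 and 474 reads. Interval edges differed by at most 3 bp between the BRD4S libraries. On the side of these intervals towards 15235519, which on the minus strand is the downstream part of the gene, each BRD4S library had 1 peak, of 5 and 4 reads.

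In the BRD4L libraries the same intervals held 3 and 4 peaks with 4 to 10 and 4 to 7 reads. Scaled by the estimated reads, the highest BRD4S pileups would correspond to 701 and 631 reads in the BRD4L libraries. Downstream of the intervals the BRD4L lists had 3 and 2 peaks, among them 15236510 to 15236658 with 10 and 7 reads. No signal as strong as the BRD4S one therefore checks the BRD4L label. The downstream BRD4L peaks did outnumber the single downstream peak of each BRD4S library, despite the lower depth of BRD4L. They held 4 to 10 and 4 to 7 reads, and whether they come from the construct was not tested. Exon positions were not used here, so the 8 intervals are described by position only.

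**Figure D1:**
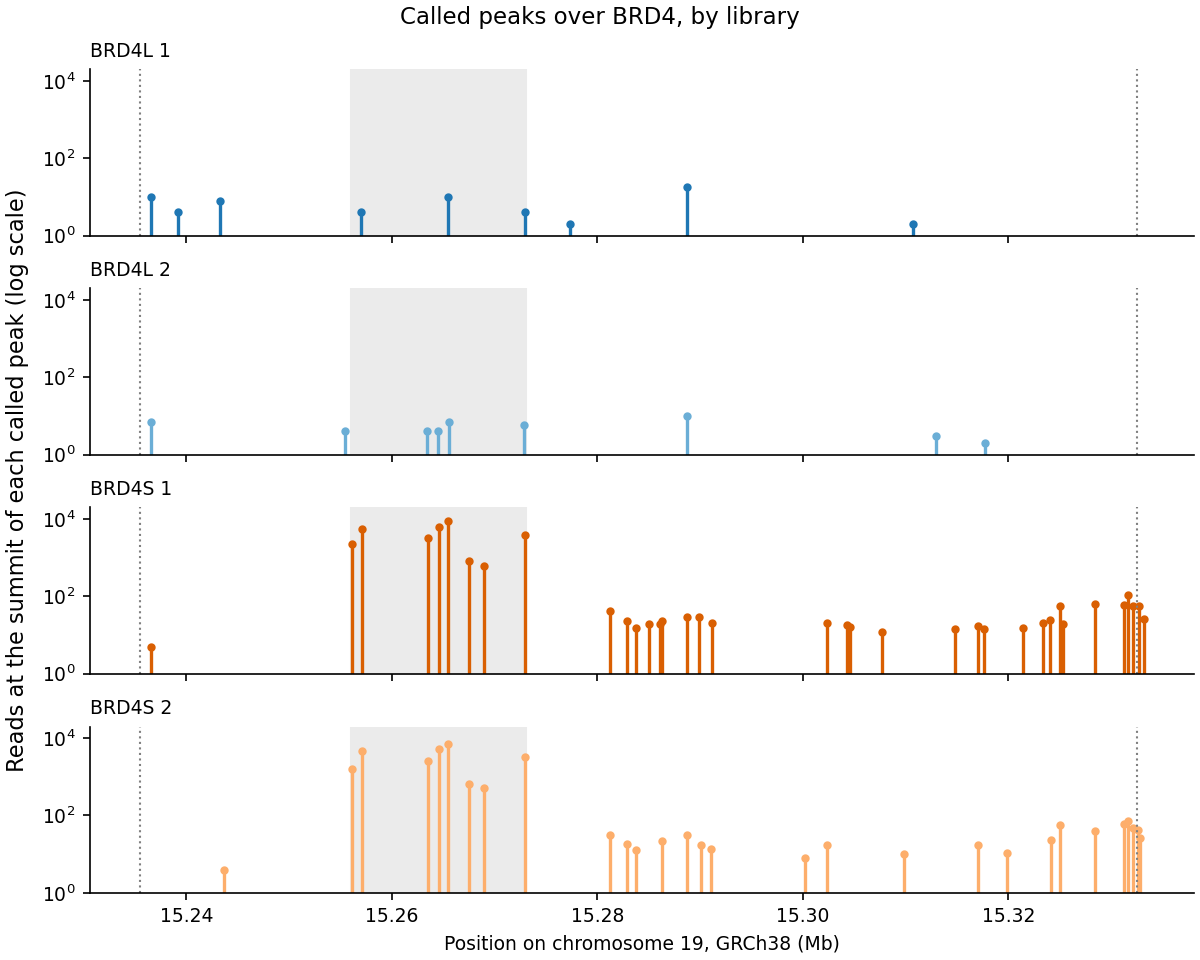
Each stem is a called peak over BRD4 in 1 library, with its position on chromosome 19 in Mb on the x axis and the reads at its summit on a log y axis; dotted lines mark the annotated gene ends and the grey band spans the 8 intervals. In the BRD4S libraries the band holds pileups of up to 8844 and 6860 reads, and in the BRD4L libraries up to 10 and 7.

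At the level of genes, 3851 protein-coding genes had a peak within 1000 bp of an annotated end in all 4 libraries, which is called shared here. Another 7324 genes had such a gene-end peak in both BRD4S libraries and in neither BRD4L library, and 202 genes showed the opposite, a number that rose to 429 and 377 without BRD4L library 1 or 2. For 2583 of the shared genes (67.1%) the highest gene-end peaks of all 4 libraries overlapped, and the others may have peaks at different ends or places. Among shared genes, the strongest by rank within each list included EIF1AX, a translation initiation factor, with 58 and 41 reads in BRD4L and 149 and 119 reads in BRD4S, and GART, an enzyme of purine synthesis, with 79, 43, 253 and 198 reads. AK2, a mitochondrial adenylate kinase, had 112 and 78 reads in BRD4L and 179 and 153 reads in BRD4S. FAM76A had 120, 68, 153 and 132 reads in the same order. Of the genes named in advance, BRD4 was shared (10, 7, 111 and 70 reads, with the BRD4L peak at 15236510 to 15236658 and the BRD4S peak at the opposite end, 15331424 to 15331802 in library 1) and so was CDK12, the kinase named in the series title (2, 3, 101 and 71 reads). MYC, an oncogene known for its sensitivity to BET inhibitors, had a gene-end peak in the BRD4S libraries alone, with 20 and 14 reads. In BRD4S library 1 it lay at 127743124 to 127743229 on chromosome 8, beyond the gene end at 127742951. The BRD4L lists held 1 and 2 peaks inside the gene. At such BRD4S pileups 1.22 to 2.25 reads would be expected at the median in a BRD4L library of equal enrichment, so a gene-end peak could have been missed.

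The other shared genes at the top of the ranking were CA5B, a mitochondrial carbonic anhydrase, RNF32, FXR2, an RNA-binding relative of the fragile X protein, and NIBAN3. CA5B had 66, 43, 66 and 57 reads, RNF32 had 50, 41, 71 and 64, and FXR2 had 68, 27, 139 and 95, in the order BRD4L 1, BRD4L 2, BRD4S 1 and BRD4S 2. For NIBAN3 (69, 33, 94 and 84 reads) the BRD4L peak lay at one end of the gene (chromosome 19, 17523814 to 17523887) and the highest BRD4S peak at the other (17555400 to 17555653). The EIF1AX peak spanned 20141812 to 20142124 on chromosome X in BRD4S library 1, the GART peak 33542761 to 33543089 on chromosome 21, the AK2 peak 33036030 to 33037151 on chromosome 1, and the CDK12 peak 39461334 to 39461998 on chromosome 17.

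Among genes with gene-end peaks in BRD4S alone, MED9, a subunit of the Mediator complex, had 153 and 114 reads (chromosome 17, 17476847 to 17477438). BRD4L peaks elsewhere in a gene were not counted, and MOK, for example, held 2 and 3. DGUOK, a mitochondrial deoxyguanosine kinase, had 144 and 124 reads (chromosome 2, 73926721 to 73927198). ADAMTS6, a secreted metalloprotease, had 126 and 107 reads, SLC30A5, a zinc transporter, 122 and 108, and DDX11, a DNA helicase, 115 and 99. MOK, a protein kinase, had 115 and 108 reads, CCDC200 had 94 and 71, and SLC71A2 had 76 and 67. For BRD4S peaks of 100 to 499 reads, 8.37 to 12.1 reads would be expected at the median in a BRD4L library of equal enrichment. A peak that was not called is not a peak shown to be absent.

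Genes with gene-end peaks in BRD4L alone were led by PPEF2, a protein phosphatase of photoreceptors, with 69 and 48 reads in an interval with the same edges in both libraries (chromosome 4, 75902569 to 75902733). BRD4S peaks elsewhere in a gene were not counted, and TMPRSS5, for example, held 2 and 4. TMEM179 had 48 and 38 reads (chromosome 14, 104590930 to 104591004), TAMALIN 42 and 31, and TMPRSS5, a serine protease, 37 and 31. TBXT, the mesodermal transcription factor brachyury, had 36 and 22 reads, TCF21, a mesenchymal transcription factor, 40 and 21, LRRN1 37 and 28, and ADM5 49 and 22. For every BRD4L-only gene named here, the gene-end interval had the same start and end in both BRD4L libraries. Copies of the same DNA fragments in both libraries would give such edges, so BRD4L binding stays open at these genes. Among the shared genes named above, RNF32, NIBAN3 and BRD4 also had identical BRD4L edges, so the same caution holds there. FAM76A, EIF1AX, CA5B, AK2, GART, FXR2 and CDK12 did not.

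Per library, 5229 and 5567 genes had a gene-end peak with BRD4L and 13696 and 13768 with BRD4S, or 26.2%, 27.9%, 68.6% and 68.9% of 19974 protein-coding genes. The BRD4S mean was 2.54 times the BRD4L mean (exact permutation test, two-sided, p = 0.333, the smallest value that 4 libraries allow). It was also 0.333 with BRD4S counted as 1 sample. The shared class was larger than the 2725 genes that independent classes of these sizes would give. With BRD4S thinned to the depth of BRD4L, an alternative chosen after the data were seen, 3939 genes had gene-end peaks in BRD4S alone and 541 in BRD4L alone.

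Gene groups fixed in advance were next compared among the genes with no BRD4L gene-end peak in either library, of which 55% had a peak in both BRD4S libraries. Genes of epithelial-mesenchymal transition (EMT) and invasion had BRD4S peaks more often, in 24 of 28 members, or 85.7% (Fisher's exact test with Benjamini-Hochberg adjustment over 27 lists, two-sided, adjusted p = 0.00349). They included ITGAV, an integrin chain, with 88 and 74 reads, SERPINE1, an inhibitor of plasminogen activators, with 99 and 77, TGFBR2, a TGF beta receptor, with 34 and 27, and SNAI2, a repressor of epithelial genes, with 41 and 30. Wnt and Notch targets had BRD4S peaks in 12 of 13 members (adjusted exact p = 0.0221), among them CTNNB1, which encodes beta-catenin, with 84 and 70 reads, and HEY2, a Notch-induced repressor, with 74 and 59. All 9 immediate early and AP-1 genes left in this background had BRD4S peaks (adjusted exact p = 0.0161), such as KLF6 with 110 and 74 reads, KLF10 with 71 and 69, and DUSP6, a phosphatase of ERK, with 22 and 23. HOX genes, the homeobox regulators of body axis identity, had them in 21 of 27 members (adjusted exact p = 0.0435), with HOXC10 at 148 and 115 reads and HOXB6 at 102 and 73.

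Groups of general cellular machinery also had BRD4S peaks more often. Every member in the background had BRD4S peaks for ribosomal proteins (17 of 17, adjusted exact p = 0.00178), cleavage and polyadenylation factors (13 of 13, adjusted p = 0.00307), cell cycle and DNA replication (12 of 12, adjusted p = 0.00349), BET proteins and transcription elongation (12 of 12, adjusted p = 0.00349) and the DNA damage response (9 of 9, adjusted p = 0.0161). RPL5, a large-subunit ribosomal protein, had 257 and 219 reads and RPL37A 159 and 138. The polyadenylation factors FIP1L1 and CSTF2 had 104 and 73 and 74 and 60 reads. TOP2A, a DNA topoisomerase, had 135 and 92 reads and BUB1, a spindle checkpoint kinase, 121 and 98. The elongation factor SUPT5H had 144 and 128 reads and MED1, a Mediator subunit, 119 and 96. PALB2 and FANCD2, which act in homologous recombination and crosslink repair, had 112 and 97 and 97 and 71 reads.

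Marker genes of other tissues had BRD4S peaks less often. This held for hepatocyte and pancreas markers (3 of 21, or 14.3%, adjusted exact p = 0.00277), blood and immune cell markers (3 of 20, or 15%, adjusted p = 0.00307) and skeletal and cardiac muscle markers (4 of 18, or 22.2%, adjusted p = 0.0198). Neuronal markers (11 of 23, adjusted exact p = 0.600) and stromal and endothelial markers (6 of 17, adjusted p = 0.225) did not pass the threshold. SYP and SNAP25, proteins of synaptic vesicle release, had 46 and 37 and 31 and 19 reads in BRD4S.

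The remaining lists did not pass the threshold in this test. Focal adhesion and actin genes (11 of 13), YAP and TEAD targets (11 of 13) and hypoxia and glycolysis genes (13 of 16) each had an adjusted exact p of 0.0849. Targets of TGF beta and SMAD had BRD4S peaks in 9 of 11 members (adjusted exact p = 0.213) and extracellular matrix genes in 18 of 26 (adjusted p = 0.254), the latter including LAMC1, a laminin chain, with 212 and 161 reads. Adjusted p was 0.314 for both p53 targets (5 of 6) and sterol and fatty acid synthesis (5 of 6), 0.422 for histones (17 of 26) and 0.437 for genes of the Mullerian and serous ovarian lineage (8 of 19). It was 0.556 for NF-kB and inflammatory cytokines (11 of 17), 0.683 for the unfolded protein and integrated stress response (3 of 4), and 0.829 for both epithelial junctions (10 of 19) and the interferon response (11 of 21). In all, 9 lists were higher, 3 lower and 15 not past the threshold.

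Genes are not replicates, and these tests describe the 4 peak sets. HOX genes lie side by side in the HOXA, HOXB, HOXC and HOXD clusters. They are therefore not independent of each other, and the p-values of this list can be too small. No list passed with a 3000 bp window or with the gene body and its flanks, where fewer members were left in the background. With the 3000 bp window the higher lists kept their shares, with EMT genes at 17 of 20 (85%), HOX genes at 13 of 14 and ribosomal proteins at 12 of 12 against 57.9% (adjusted exact p = 0.0659, 0.0659 and 0.0529), and all members of the polyadenylation (9), cell cycle (8), BET and elongation (7) and DNA damage (7) lists had BRD4S peaks. Of the lower lists, blood and immune markers (7 of 15, 46.7%) and muscle markers (6 of 14, 42.9%) came closer to the 58.0% of other genes, and hepatocyte and pancreas markers stood at 5 of 18 (27.8%). With the gene body and flanks each of the 9 higher lists had BRD4S peaks in all of its 1 to 9 members left, against 52.4% to 52.5%. Hepatocyte and pancreas (6 of 12) and blood and immune markers (2 of 4) then stood at 50%, close to the 52.5% of other genes, so their lower share was not seen there. Muscle markers stood at 2 of 7. Lists left with 1 to 9 members, higher or lower, say little. After thinning of the BRD4S lists the calls for EMT and invasion (35.7%), immediate early and AP-1 (44.4%), Wnt and Notch (30.8%), HOX (44.4%) and muscle genes (16.7%) were lost, against 29.6% of other genes. The EMT call (60.7%) and the Wnt and Notch call (64.3%) were also lost with lists of equal length, where 45.6% of other genes had BRD4S peaks, and the DNA damage call with gene-length matching (9 against 5.93 expected, permutation test, adjusted p = 0.105). Histones were gained with gene-length matching, at 17 against 6.91 expected (permutation test, adjusted p = 0.00270). When single libraries were left out, HOX genes no longer passed without BRD4L library 1 (75.9% against 56.9%, adjusted exact p = 0.0724) or BRD4S library 1 (77.8% against 58.6%, adjusted p = 0.104), nor Wnt and Notch targets without BRD4L library 2 (86.7% against 57.3%, adjusted p = 0.0635). Their shares and those of other genes stayed close to the main ones, so these are changes at the threshold. Muscle markers without BRD4S library 2 stood at 38.9% against 58.2% (adjusted exact p = 0.237). The HOX call was also lost with at least 5 reads (78.1% against 60.0%, adjusted exact p = 0.0682). Tested without the BRD4L libraries, HOX genes stood at 32 of 39 against 66.0% (adjusted exact p = 0.0503).

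Genes with peaks in all 4 libraries were compared in the same way, against 19.3% of all protein-coding genes. BET proteins and transcription elongation factors were shared more often, in 19 of 35 members (54.3%, adjusted exact p = 0.000112). CCNT1, the cyclin of the elongation kinase CDK9, had 91, 39, 77 and 60 reads in BRD4L 1, BRD4L 2, BRD4S 1 and BRD4S 2, the elongation factor ELL had 58, 48, 112 and 84, and HEXIM1, an inhibitor of that kinase, had 9, 7, 99 and 92. Sterol and fatty acid synthesis genes were shared in 14 of 24 members (adjusted exact p = 0.000356), including ACLY with 39, 19, 80 and 71 reads and INSIG1, a regulator of sterol sensing, with 9, 11, 100 and 82. Targets of p53 were shared in 12 of 21 (adjusted exact p = 0.000982), with TIGAR at 7, 7, 69 and 64 reads and FDXR at 12, 13, 39 and 36. The unfolded protein and integrated stress response was shared in 13 of 24 (adjusted exact p = 0.000982), including HSPA5, an endoplasmic reticulum chaperone, with 23, 12, 149 and 125 reads. At CCNT1, INSIG1 and FDXR the BRD4L peak had identical edges in both BRD4L libraries, so copied fragments stay open there. The other genes named in this paragraph did not have such edges.

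Ribosomal protein genes (18 of 40, adjusted exact p = 0.00100) and immediate early and AP-1 genes (11 of 23, adjusted p = 0.00821) were also shared more often. RPS11 had 27, 37, 141 and 105 reads, and the AP-1 subunits JUND and FOSL2 had 43, 37, 122 and 97 and 10, 11, 122 and 98. Focal adhesion and actin (11 of 26), cell cycle and DNA replication (12 of 30) and the DNA damage response (11 of 26) each had an adjusted exact p of 0.0262. Examples were VCL, which encodes vinculin (6, 9, 120 and 92 reads), CDK4, a kinase of the G1 phase (73, 46, 166 and 140), and FANCA, of the Fanconi anaemia pathway (10, 6, 111 and 86). Shared less often were EMT and invasion (1 of 31, adjusted exact p = 0.0459), hepatocyte and pancreas markers (0 of 23, adjusted p = 0.0345) and neuronal markers (0 of 25, adjusted p = 0.0262). The 1 shared EMT gene was AXL, a receptor tyrosine kinase, with 10, 10, 16 and 15 reads, and its BRD4L peak (chromosome 19, 41262570 to 41262718) lay at the opposite gene end from its highest BRD4S peak (41219396 to 41219502).

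The other 15 lists did not pass. Adjusted p was 0.0829 for TGF beta and SMAD targets (8 of 20), 0.0902 for blood and immune markers (1 of 27), 0.119 for epithelial junctions (1 of 24) and muscle markers (1 of 25), 0.120 for cleavage and polyadenylation (9 of 26) and 0.125 for hypoxia and glycolysis (9 of 27). It was 0.151 for stromal and endothelial markers (1 of 23), 0.154 for Wnt and Notch targets (8 of 24), 0.241 for extracellular matrix (3 of 34) and 0.257 for the Mullerian and serous ovarian lineage (2 of 26). For the interferon response (3 of 29) it was 0.403, for YAP and TEAD targets (6 of 22) 0.465, for histones (9 of 42) 0.752, for NF-kB and cytokines (4 of 25) 0.836 and for HOX genes (7 of 39) 1. PCF11, a polyadenylation factor shared between the isoforms, had 26, 11, 90 and 70 reads, and HOXC13 had 5, 5, 88 and 67.

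All 12 of these calls were lost when members were compared with other genes that had peaks in both BRD4S libraries at equal BRD4S pileup, a test chosen after the data were seen: 0 lists were higher and 0 lower, and 2 had an unadjusted permutation p under 0.05. EMT genes were then shared in 1 of 27 against 5.48 in the permuted lists (permutation test, adjusted p = 0.354). Hepatocyte and neuronal markers were left with 3 and 11 members, of which 0.31 and 1.66 would be expected to be shared. Both had 0 shared, the lowest possible, so this test could not have kept their lower calls. The cell cycle call was also lost with gene-length matching (12 against 6.36 expected, permutation test, adjusted p = 0.0733), and the EMT call without BRD4L library 1 (9.68% against 25.0%). With a −log10 q-value of at least 5, the calls for BET and elongation (20.0%), p53 targets (19%), DNA damage (11.5%) and focal adhesion genes (15.4%) and all 3 lower calls were lost, but only 8.53% to 8.56% of other genes were then shared. BET and elongation genes were still at 2.35 times (adjusted exact p = 0.102) and p53 targets at 2.23 times the share of other genes (adjusted p = 0.297). Focal adhesion and DNA damage genes were at 1.80 and 1.35 times (adjusted exact p = 0.413 and 0.594). With at least 5 reads, the calls for p53 targets (23.8%), focal adhesion (15.4%), DNA damage (11.5%) and all 3 lower calls were lost, against 9.83% to 9.86% of other genes. DNA damage genes were then at 1.17 times (adjusted exact p = 0.738). After thinning, the calls for focal adhesion (26.9%), immediate early and AP-1 (30.4%), neuronal (0%) and hepatocyte markers (0%) were lost, against 14.2% to 14.3% of other genes. With a 3000 bp window those for EMT (12.9%), DNA damage (46.2%) and neuronal genes (8%) were lost, against 28.0% of other genes. With the gene body and flanks 58.8% of other genes were shared, and the calls for ribosomal proteins (65%), cell cycle (66.7%), p53 (76.2%), DNA damage (76.9%), immediate early (82.6%), sterol (83.3%) and EMT genes (54.8%) were lost. Neuronal markers stood at 64.0%, near the share of other genes (adjusted exact p = 0.806). Ribosomal and cell cycle genes were then at 1.11 and 1.13 times the share of other genes.

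No list stood apart among the genes with gene-end peaks in BRD4L alone (Fisher's exact test, 0 higher, 0 lower and 0 with an unadjusted p under 0.05). This says little, since 7 lists had no member and 8 had 1 or 2 in the background, and 0 hits would not have given an unadjusted p under 0.05 in any list. The 5 list members in that class were CLDN3, a tight junction protein, with 5 and 2 reads, MUC16, which encodes the ovarian cancer marker CA-125, with 4 and 9, IRF7, an interferon regulatory factor, with 46 and 18, FGG, a fibrinogen chain, with 2 and 2, and MYH7, a muscle myosin, with 2 and 2.

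**Figure D2:**
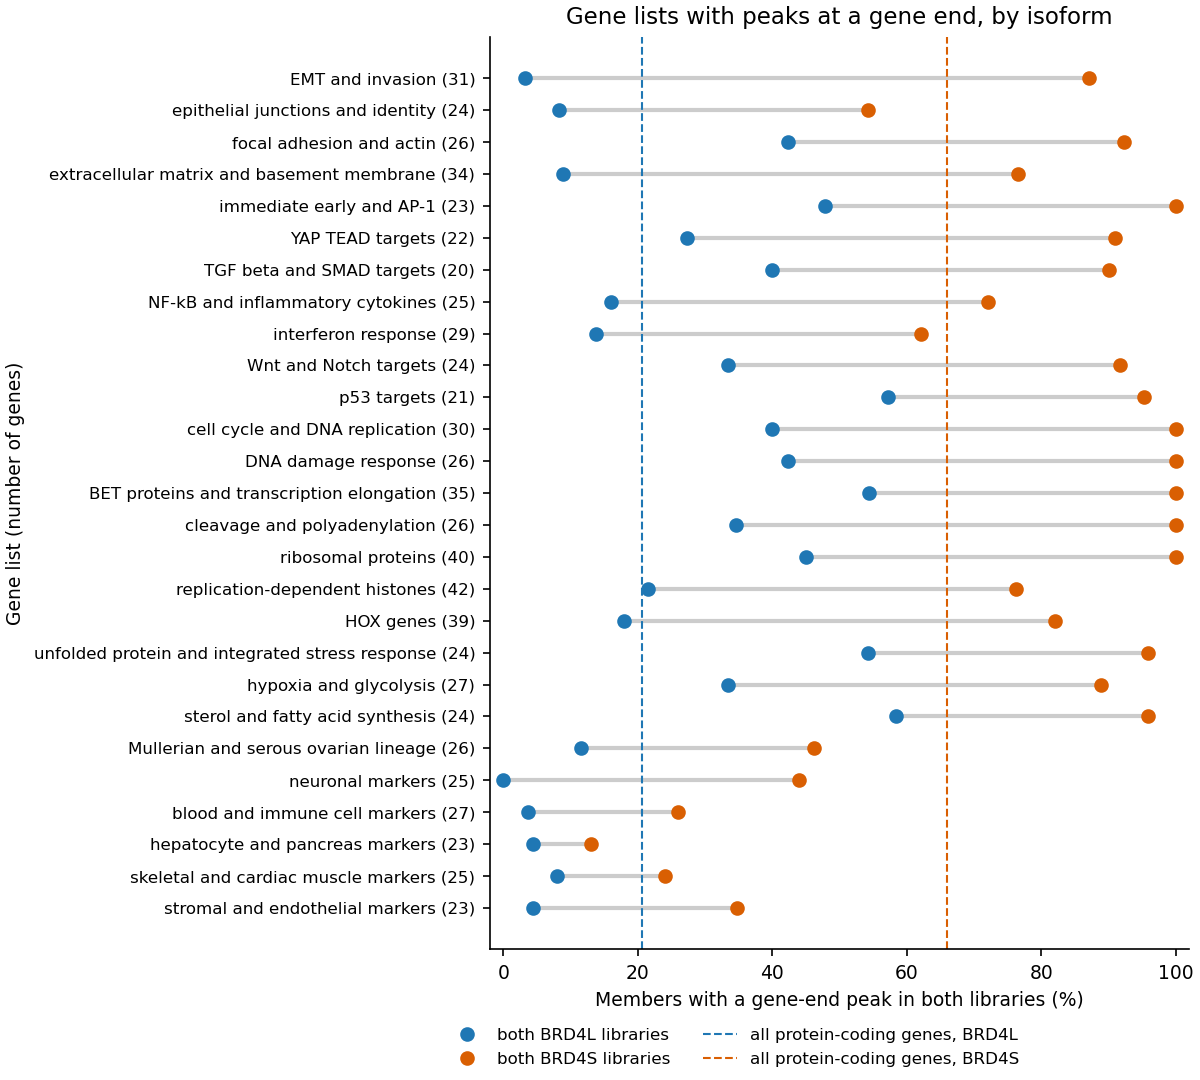
For each of the 27 gene lists (number of genes in brackets on the y axis), points give the percentage of members with a gene-end peak in both BRD4L libraries (blue) and in both BRD4S libraries (orange), and dashed lines give the same for all protein-coding genes. EMT and invasion genes lie at 3.23% and 87.1%, and hepatocyte and pancreas markers at 4.35% and 13%, against 20.7% and 66.0% of all genes.

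Merging the 4 lists gave 208281 regions, and most of those found in more than 1 library were found in both libraries of 1 isoform. The libraries of an isoform were also similar in depth and may be technical repeats. Isoform, sample and depth can therefore not be separated in this pattern. Both BRD4S libraries and neither BRD4L library had a peak in 65463 regions (31.4%), both BRD4L libraries alone in 14565 (6.99%), and all 4 libraries in 5100 (2.45%). Pairs that mixed the isoforms gave 261 to 388 regions. Shared regions were broad, with a median width of 498.5 bp and median pileups of 54 and 42 reads in BRD4S but 5 and 5 in BRD4L. BRD4S-only regions had a median width of 179 bp and 17 and 13 reads, and BRD4L-only regions 99 bp and 3 and 3 reads.

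Gene ends were far more frequent in the shared regions than elsewhere. Of shared regions 57.6% lay within 1000 bp of a gene end (95% Wilson interval 56.2 to 58.9, counting error only), 24.1% in gene bodies and 18.3% between genes. BRD4S-only regions lay at gene ends in 27.3% (27 to 27.6) and in gene bodies in 43.9%. BRD4L-only regions lay at gene ends in 4.19% (3.87 to 4.53), in gene bodies in 49.3% and between genes in 46.5%, against 2.40%, 40.2% and 57.4% of the genome. Fisher's exact test gave odds ratios of 3.61 for shared against BRD4S-only regions and 8.59 for BRD4S-only against BRD4L-only regions. Thinning of the BRD4S lists moved the gene-end share of BRD4S-only regions to 47.5%. With 1 library of an isoform taken as enough, the BRD4L-only regions numbered 55045, and without BRD4L library 1 or 2 they numbered 36565 and 33082.

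**Figure D3:**
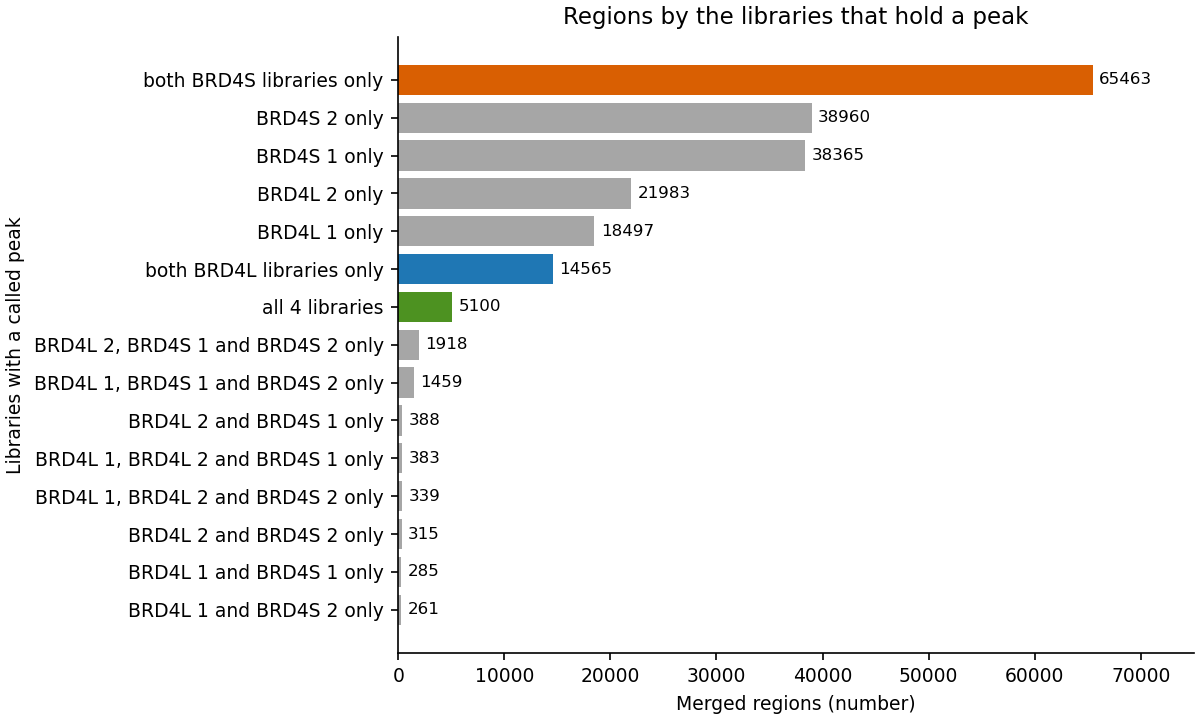
Bars give the number of merged regions (x axis) by the set of libraries that hold a called peak (y axis), with both BRD4S libraries alone in orange, both BRD4L libraries alone in blue and all 4 libraries in green. The bar for both BRD4S libraries alone reaches 65463 regions and the 4 mixed pairs lie between 261 and 388.

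Peaks of one BRD4L library overlapped the other in 49.8% and 45.2% of cases, and those of the BRD4S libraries in 65.8% and 66.2%. Between isoforms 17.4% to 18% of BRD4L peaks overlapped a BRD4S peak and 6.05% to 6.73% of BRD4S peaks overlapped a BRD4L peak, against 0.335% to 1.58% for peaks placed at random in all pairs. Jaccard indices of the covered bases were 0.325 within BRD4L, 0.557 within BRD4S and 0.0347 to 0.0379 between the isoforms. The 6 pairs come from 4 libraries, so no p-value is given. The BRD4L libraries shared 12639 intervals with identical start and end, the BRD4S libraries 2413, and pairs across isoforms 4 to 14.

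BRD4S peaks gathered in the HOX loci. The HOXA cluster (chromosome 7, 27092993 to 27200091) held 81 and 72 peaks in the BRD4S libraries and 7 and 9 in the BRD4L libraries, or 19.8 and 17.2 times and 4.81 and 5.62 times the genome-wide density of each list. The HOXC cluster (chromosome 12, 53938831 to 54056030) held 75 and 72 peaks with BRD4S and 9 and 6 with BRD4L, and the HOXB cluster (chromosome 17, 48528526 to 48728750) held 84 and 76 against 7 and 10. At HOXD (chromosome 2, 176087487 to 176190907) there were 32 and 36 against 6 and 5. These loci were singled out after the peak clusters had been ranked, since the 3 most populated clusters of each BRD4S list covered HOXA, HOXB and HOXC. The densities were not tested.

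Clusters of at least 3 peaks spaced by less than 10000 bp numbered 1517 and 1964 with BRD4L and 14934 and 14881 with BRD4S, an 8.57-fold difference of the means. Peaks shuffled on their chromosomes gave 726, 925, 8803 and 9117. The share of peaks in clusters was 12.9%, 15.5%, 72.0% and 65.7%, against 5.65%, 6.58%, 28.3% and 28.4% after shuffling. Peak number differed 2.70-fold between the isoforms, covered sequence 4.68-fold (4.49 and 4.91 Mb against 22.7 and 21.3 Mb) and median width 1.25-fold (97 and 96 bp against 125 and 117 bp). At gene ends lay 12.4% and 12.3% of the BRD4L peaks and 24.1% and 23.3% of the BRD4S peaks, a difference of 11.4 percentage points, against 2.86% to 3.04% for shuffled peaks.

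All of these differences were larger than the spread between libraries of one isoform, and each had p = 0.333 in the exact two-sided permutation test, the smallest value possible with 4 libraries. Several of them turned, shrank or grew under other settings. After thinning to the BRD4L depth the ratio of peak numbers was 0.657 and that of cluster numbers 1.26, while the gene-end difference was 27.2 points. With lists of equal length, 12.4% and 12.1% of BRD4L peaks and 40.6% and 41.8% of BRD4S peaks lay at gene ends. Among peaks with at least 5 reads in every list, the gene-end difference was -0.854 points. That cut does not equalise depth, since it kept 9335 and 8032 BRD4L peaks but 112203 and 97039 BRD4S peaks.

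Thinning to the estimated BRD4L read number left a gap at the strongest BRD4S peaks, which include those of MED9, DGUOK and RPL5. Of BRD4S library 1 peaks with 100 to 499 reads, 96.7% and 95.6% still passed the BRD4L threshold after thinning to the depth of BRD4L library 1 and 2, but 48.0% and 50.6% overlapped a peak of these libraries. For BRD4S library 2 the values were 99.2% and 98.9% against 52.1% and 55.4%. Over all peaks with at least 50 reads, 78.6%, 76.0%, 88.9% and 87.1% passed after thinning and 29.8%, 31.5%, 35.3% and 37.1% overlapped a BRD4L peak. BRD4 itself was left out, and the comparison was added after the data had been seen.

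**Figure D4:**
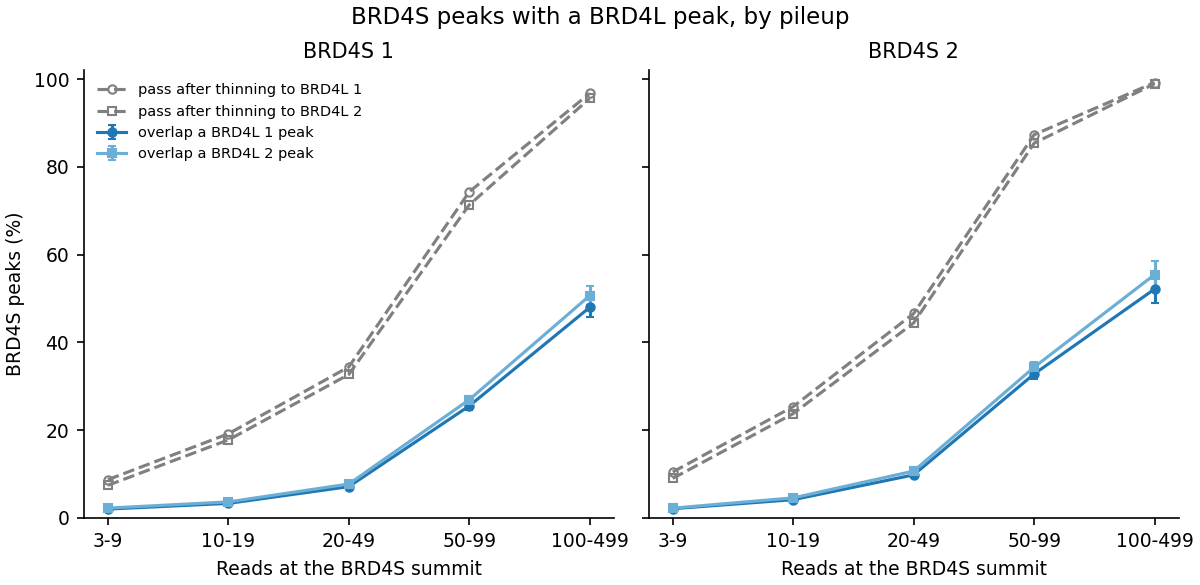
BRD4S peaks are grouped by the reads at their summit (x axis, panels for BRD4S 1 and BRD4S 2), with the percentage that overlaps a peak of each BRD4L library in blue (bars are 95% Wilson intervals) and the percentage that passes after thinning to that library's depth in grey. At 100 to 499 reads the blue points lie between 48.0% and 55.4% and the grey points between 95.6% and 99.2%.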

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

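Thinning, a minimum pileup, the removal of flat-topped or BRD4 peaks, gene-length matching, the BRD4L libraries left unused and matching on BRD4S pileup were chosen after the data were seen, and the others were planned. Of the values compared over the alternatives, 185 stayed within their limits, 80 moved and 2 turned, and of the percentages for single gene lists 199 kept their side of the threshold, 64 lost it and 1 turned. The cause of a change was not tested unless it follows from the alternative itself, as with fewer peaks or fewer libraries. Motif shares and matching on promoter GC content were not run. Low depth in the BRD4L libraries limits every statement on missing BRD4L peaks, since many of their calls rest on 2 reads.

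With a −log10 q-value of at least 5, the BRD4S to BRD4L ratio was 7.34 for peak number, 14.0 for covered sequence, 99.96 for clusters and 5.43 for genes per library. Overlap was then 68.1% within BRD4L, 78.3% within BRD4S and 18.2% between isoforms. There were 2069 shared and 3807 BRD4L-only regions, 1707 shared and 81 BRD4L-only genes, 15 lists higher and 5 lower among BRD4S-only genes, and 5 higher and 0 lower among shared genes. With lists of equal length the ratio was 2.94 for covered sequence, 2.41 for median width and 3.50 for clusters, the gene-end difference was 28.9 points, BRD4S overlap 84.0%, BRD4S-only regions 26854 and BRD4L-only genes 353.

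Leaving out each library in turn gave 14954 to 36565 BRD4L-only regions, 66943 to 108746 BRD4S-only regions and 239 to 429 BRD4L-only genes, since a single library was then enough for a class. With 1 library of an isoform enough in general, 10448 regions were shared, 142788 BRD4S-only and 55045 BRD4L-only. An overlap of 50% of both peaks gave 54.6% within BRD4S, 3.19% between isoforms and 944 shared regions. A spacing of 5000 bp gave a cluster ratio of 27.1 and one of 20000 bp gave 3.71.

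A 3000 bp window put 11.4% of BRD4L-only regions at gene ends, with 0 lists higher and 0 lower among BRD4S-only genes and 1 lower among shared genes. A 500 bp window gave a gene-end difference of 7.34 points. With gene bodies and flanks, 11747 genes were shared and 2130 BRD4S-only, the ratio of genes per library was 1.22, and 0 lists were higher and 0 lower among BRD4S-only genes and 5 higher among shared genes. Neuronal markers turned there, with 64.0% of members shared against 58.8% of other genes. That difference did not pass the threshold (adjusted exact p = 0.806).

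After thinning of BRD4S, the ratio was 0.657 for peak number, 1.91 for covered sequence, 2.22 for width and 1.26 for clusters, and the gene-end difference 27.2 points. BRD4S overlap was 47.1%, with 2632 shared and 9219 BRD4S-only regions, of which 47.5% lay at gene ends, against 6.30% of BRD4L-only regions. BRD4S-only genes numbered 3939 and BRD4L-only genes 541, and 1 list was lower among shared genes. With at least 5 reads, the ratio was 12 for peak number, 17.8 for covered sequence, 80.6 for clusters and 5.31 for genes per library, and the gene-end difference -0.854 points. Overlap was 72.4% within BRD4L, 70.8% within BRD4S and 21.4% between isoforms, with 2528 shared and 3468 BRD4L-only regions, 1966 shared and 58 BRD4L-only genes, and 0 lists lower among shared genes. Without flat-topped peaks, overlap was 54.1%, 64.6% and 20.3%, with 4005 BRD4L-only regions and 78 BRD4L-only genes. With the BRD4L libraries unused, 15 lists were higher and 6 lower for BRD4S peaks, and with matching on BRD4S pileup 0 were higher and 0 lower among shared genes.

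With libraries paired by replicate number as a block, the mean differences were 73552 peaks, 17.3 Mb, 24.5 bp, 13167 clusters, 8334 genes and 11.4 points, equal to the unpaired differences. The exact sign-flip test gave p = 0.5 for each, the smallest value that 2 pairs allow. Nothing in the labels says that equal numbers share a day or culture.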

Other observations

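Which gene groups had BRD4S peaks at all can be asked without the BRD4L libraries, a test chosen after the data were seen. Peaks were called without a control library, so a peak by itself does not show BRD4S binding. Measured against all protein-coding genes, of which 66.0% had a gene-end peak in both BRD4S libraries, 15 lists were higher and 6 lower (Fisher's exact test with Benjamini-Hochberg adjustment). All 23 immediate early and AP-1 genes, 30 cell cycle genes, 26 DNA damage genes, 35 BET and elongation genes, 26 polyadenylation factors and 40 ribosomal protein genes had peaks. Lower were the markers of hepatocytes and pancreas (13%), muscle (24.0%), blood and immune cells (25.9%), stroma and endothelium (34.8%) and neurons (44.0%), and also genes of the Mullerian and serous ovarian lineage (46.2%, adjusted exact p = 0.0496). XBP1, a transcription factor of the unfolded protein response, had 179 and 177 reads, SREBF1, a regulator of lipid synthesis, 132 and 93, and CDKN1A, a cell cycle inhibitor induced by p53, 62 and 58.

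Technical explanations were set against the isoform for the BRD4S peaks, by their number and by strong ones without a BRD4L peak, for the BRD4L-only regions and for the BRD4 locus. All of these tests were chosen after the data had been examined. Those on peak number and strong BRD4S peaks were fixed before their own results were computed, and those on the BRD4L-only regions and the BRD4 locus after.

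The larger number of BRD4S peaks could come from depth. Thinned to the mean BRD4L depth, the BRD4S lists held a mean of 28460 peaks, below the higher BRD4L number of 45326. Thinning only drops called peaks and cannot add 2-read calls, which made up 51.7% and 57.5% of the BRD4L peaks. It may therefore understate a shallow BRD4S list, and whether depth alone accounts for the larger number stays open. For strong BRD4S peaks without a BRD4L peak, those of 50 reads or more, the share that passed after thinning exceeded the share with a BRD4L peak by at least 44.5 percentage points in the 4 library pairs, which argues against depth as the whole cause. Stacks of reads with equal ends were looked for as flat-topped peaks, whose summit lies within 1 bp of the peak centre. Their summits held at most 7.751% of the estimated BRD4L reads. The summits of all BRD4L peaks together held only 15.6% and 14.9%, so this measure could not have reached a large share and leaves such stacks open. Open and untested remain a difference between the isoforms, lower expression or weaker enrichment of the BRD4L construct, and library preparation, which cannot be separated from the isoform because the shortest peak width was 73 bp in both BRD4L lists and 66 bp in both BRD4S lists.

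Regions seen in both BRD4L libraries alone lay mostly away from gene ends, and 69.2% held an interval with the same edges in both, against 3.33% of BRD4S-only regions. Among peaks of 10 to 50 reads, 75.6% and 72.6% of BRD4L peaks had identical edges in the other BRD4L library, against 2.31% and 2.62% of BRD4S peaks, so that the lowest BRD4L share was 27.67 times the highest BRD4S share; among BRD4L-only regions with 2 reads in the lower library, 7588 of 14565, the share with such an interval was 60.1%. Copies of the same fragments in both BRD4L libraries would give such edges, for instance from a shared pool of DNA or from plasmid or other foreign DNA, which was not tested further. The share of regions with an identical interval rose with the reads. Among BRD4L-only regions with 3 to 4, 5 to 9 and 10 to 50 reads in the lower library it was 67.8%, 87.9% and 94.8%. Of regions with at least 3 reads in both BRD4L libraries, 60.09% had no BRD4S peak. The lower 95% Poisson limit of the reads predicted for BRD4S there was 47.0 and 34.9 at the median. This argues against too little BRD4S depth only where the BRD4L reads are independent, since copied fragments would raise the prediction. For BRD4L-only regions with 2 reads in the lower library the lower of these medians was 6.882, from pileups at the minimum for a call, so too little BRD4S depth stays open there, and BRD4L binding stays open, untested, for all of these regions.

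The narrow intervals inside BRD4 may hold reads from the BRD4S expression construct. In the BRD4S libraries the highest pileup there was at least 79.68 times the highest pileup at an end of the gene, and interval edges differed by at most 3 bp. Nearly no BRD4S signal lay downstream of the intervals, where the full-length form has its additional coding sequence. The BRD4L libraries showed 10 and 7 reads at most in these intervals, whereas 701 and 631 reads would be predicted from depth at an equal construct dose. Downstream of the intervals the BRD4L lists held 3 and 2 peaks, of at most 10 and 7 reads, and their origin was not tested. A different vector or codon-altered sequence for BRD4L remains open and was not tested.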
